A study of Mus musculus with 2 samples.

How the data were processed

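RNA from mouse lung was measured on 2 one-colour arrays, 1 for wild-type and 1 for Rosa26-Foxm1 mice. Per the labels' protocols, total RNA was isolated with RNA STAT reagent, cleaned on columns with DNase treatment and checked on a Bioanalyzer, and cRNA labelled with digoxigenin was made with an Applied Biosystems chemiluminescent kit. Per the labels, each array held RNA of left lung lobes pooled from 3 mice. Per the series design, 7 mice of each group were killed at each of the times 12 and 24 weeks after the carcinogen. Lungs taken at the later time were not analysed here.

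The values the authors deposited are linear probe intensities, 1 per probe and array, and their image software, background correction and normalisation are not given in the sources used here. Both columns had a median of 1.00, so the deposited intensities were already scaled to about each array's own median. The other quantiles differed, with 95th percentiles of 67.5 in wild-type and 71.8 in Rosa26-Foxm1 lung, so the columns were not quantile normalised. Pearson's r of the log2 values was 0.959 over all probes and 0.941 over measured probes. The 100 brightest probes held 18.6% of the total intensity on the wild-type array and 18.4% on the other. No detection calls were used here.

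Probes were named from the platform annotation, updated through the gene ID to RefSeq symbols. Of 33012 probes, 14411 had 1 gene, 247 had several and were not named, and 18354 had no gene listed in the table used here. Of 13840 named genes, 13832 matched a RefSeq gene ID of the mouse assembly GRCm38.p6, and 540 had more than 1 probe. That assembly served for names, gene length and neighbouring genes, and no coordinates are given because no build is named with the values.

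The following choices were made before the data were examined. Values were quantile normalised between the 2 arrays, values below the 50th percentile of an array (a normalised intensity of 1.00) were set to that floor, and log2 was taken. A gene was measured if it was above the floor on at least 1 array, and was represented by its probe with the highest mean. Differences are Rosa26-Foxm1 minus wild type. Where the dimmer array was below the floor, a fold is a lower bound and is written as at least that fold, and a log2 difference is likewise a bound on its size. Genes at least 2-fold apart were counted. The 32 gene lists, with 1.5-fold as the size for members, were also fixed then. Each list's median was placed among the medians of 10000 random lists of the same size, drawn from 20 classes of mean expression, if at least 3 members were measured. The lists cover G2 phase and mitosis, S phase, p53 targets, lung epithelial, immune, endothelial and stromal cell types, cytokines and chemokines, interferon, MHC class II, xenobiotic metabolism, growth factors, handling, clock, carried-along tissues, reference, sex-linked, ribosomal and respiratory chain genes.

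The genes named in the text were chosen by a rule. It takes Foxm1, the 10 genes with the largest and the 10 with the smallest difference among those whose brighter array was above the 75th percentile, and up to 3 members at each end of every list. Genes with a clone, predicted or locus symbol, or whose other measured probes had another sign, were left out of the first part. Ranks use floored differences, so genes below the floor on 1 array could stand higher. It also takes fixed markers of proliferation and lung cell types and the reference genes Actb, Gapdh and Hprt wherever they were measured. No probe carried Xist alone.

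There is 1 array per group, so no p-value is given and the number of arrays limits the precision. The spread between probes of a gene is the only error that could be measured. Among 317 genes with at least 2 measured probes, of which 2 were taken per gene, 12 had at least 1 of these past 2-fold. In 8 of the 12 genes both probes taken had the same sign. Over all measured genes with several measured probes, 106 had probes that differed in sign. On simulated data with noise of the size of the probe SD and no change, 4 genes of 9237 were 2-fold higher and 12 lower. With genes changed 2-fold, 41% of them were called, and 94% of those changed 4-fold. Unchanged lists of 25 genes were outside the middle 95% of random lists in 5% of draws. These lists were themselves drawn at random from the same genes, so such a share follows from their construction and does not cover lists of related genes. With 0.3 log2 added to their medians, they were above the middle 95% in 98%. These simulations hold no correlation between genes and no difference between mice. Their noise was normal and of 1 size for all probes, though the probe SD was 0.39 for dimmer and 0.23 for brighter pairs. They therefore do not give the number of 2-fold genes that noise produced in the measured data.

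Alternatives were median scaling, the deposited values, loess on the log ratio (span 0.3), floors at the 25th and 75th percentiles and none, the median over the probes of a gene, sizes of 1.5-fold and 3-fold, the mean in place of the median, and lists without shared genes. Correction of the differences for their trend with genomic gene length was added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.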

Results

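Gene expression was measured in mouse lung 12 weeks after a chemical carcinogenesis protocol, on 1 array of wild-type lung and 1 array of lung from Rosa26-Foxm1 mice. Rosa26-Foxm1 mice are transgenic for Foxm1, a forkhead transcription factor that drives genes of G2 phase and mitosis. All mice had received a single intraperitoneal dose of the carcinogen 3-methylcholanthrene (15 µg per g body weight). Butylated hydroxytoluene, a lung tumour promoter, was then injected 6 times at weekly intervals, at 150 µg/g first and 200 µg/g afterwards. Each array was hybridised with RNA pooled from the left lung lobes of 3 mice. The wild-type mice were FVB/N males by their labels, while the labels used here give neither sex nor strain for the Rosa26-Foxm1 mice. The array held 33012 probes, and deposited intensities ran from 0.0294 to 2820 on the wild-type array and from 0.0510 to 2268 on the Rosa26-Foxm1 array, with medians of 1.00 on both. Of 13840 named genes, 9516 were above the floor, set at the median intensity, on at least 1 array, and 8586 on both. With 1 array per group there is no spread between replicates, and no test between the genotypes was possible. The only measure of error is the probe SD, the error of the log2 difference of a single probe. It is the SD between 2 probes of the same gene divided by the square root of 2. The probe SD was 0.32 over 317 genes with at least 2 measured probes (0.39 for dimmer and 0.23 for brighter pairs), with 2 probes taken per gene. It used floored values, so differences cut off at the floor can make it too small. It leaves out differences between mice and errors that the probes of an array share.

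The comparison asks how the lung transcriptome of Rosa26-Foxm1 mice differed from that of wild-type mice under the same carcinogen protocol. Macrophage, cytokine and chemokine genes were higher as groups in Rosa26-Foxm1 lung, with Gpnmb, Mmp12 and Cxcl1 at 21.4-fold, 11.0-fold and 10.8-fold. The macrophage genes did not move alike. Of 25 measured, 12 were at least 1.5-fold higher, 2 lower and 11 between, and Siglecf was 2.39-fold lower. Endothelial markers were lower, with a median log2 difference of -0.59 over 29 genes. Genes of mitosis were higher by a small amount, with a median of 0.27 over 28 genes, and Birc5 and Aurka were more than 2-fold higher. Aurka was close to the floor in wild-type lung. Of 9516 measured genes, 188 were at least 2-fold higher and 144 at least 2-fold lower, together 3.49% of the genes. Of the 188 higher genes, 71 were below the floor in wild-type lung. Of the 144 lower genes, 53 were below the floor in Rosa26-Foxm1 lung. Over all measured genes the median difference was -0.06, and the 5th and 95th percentiles were -0.71 and 0.69.

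Foxm1 itself was close to the floor of 1.00 on both arrays. Its single probe had a normalised intensity of 1.13 in wild-type and 1.23 in Rosa26-Foxm1 lung, a log2 difference of 0.11 (1.08-fold), which is smaller than the probe SD of 0.32. Whether this probe matches the sequence of the transgene is not given in the sources used here, so its value does not check the genotype labels.

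Among the brighter genes above the floor on both arrays, the largest difference upward was in Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, at 5.86 in wild-type and 125 in Rosa26-Foxm1 lung (21.4-fold). Lcn2, an iron-siderophore binding protein of neutrophils and inflamed epithelium, was at 65.4 against 998 (15.3-fold). Mmp12, the macrophage elastase, was 11.0-fold higher, the neutrophil chemoattractant Cxcl1 10.8-fold and the acute phase protein Saa3 10.6-fold. Jchain, the joining chain of polymeric immunoglobulins, was 8.33-fold higher at 49.3 against 411. Other genes were low in wild-type lung. Tnfrsf9, a costimulatory receptor of T cells, was 11.1-fold higher, the anion exchanger Slc26a4 10.6-fold and Bex1 7.80-fold. Wnt10a, a secreted Wnt ligand, was below the floor in wild-type lung and at least 19.0-fold higher in Rosa26-Foxm1 lung. It rests on a single probe, whose deposited wild-type intensity of 0.0294 was the lowest on that array. Whether that spot was faulty was not checked.

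In the other direction, Denn2b was 63.3-fold lower by a single probe, whose deposited intensity was 295 in wild-type and 4.92 in Rosa26-Foxm1 lung. Probe sequences were not used here, so the target of this probe was not checked. The olfactory receptor gene Olfr1086 was at least 19.7-fold lower, with the Rosa26-Foxm1 array below the floor. Cyp1a1, the aryl hydrocarbon receptor target that metabolises polycyclic hydrocarbons, was 5.82-fold lower (8.80 against 1.51), and the zinc and iron transporter Slc39a14 5.65-fold lower. The remaining genes named for their size, Papss2, Kank2, Adgre4, Mapk14, Fas and Klhl5, were between 2.52-fold and 2.66-fold lower. Mapk14 encodes the stress kinase p38 alpha and Fas a death receptor.

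**Figure D1:**
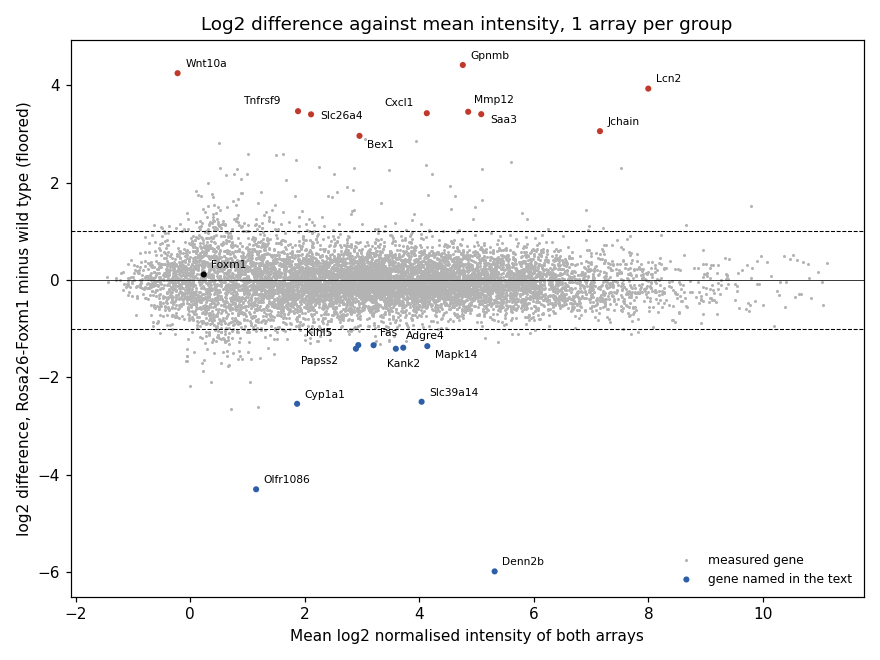
Log2 difference (Rosa26-Foxm1 minus wild type, values below the floor set to it) against the mean log2 normalised intensity of both arrays, 1 point per measured gene, with dashed lines at a 2-fold difference. The 10 genes named for the largest difference upward are red, the 10 downward are blue and Foxm1 is black; Gpnmb lies at 4.42, Denn2b at -5.98 and Foxm1 at 0.11.

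Of 28 measured genes of G2 phase and mitosis, many of them known Foxm1 targets, 20 were above 0 and 8 below. Their median log2 difference of 0.27 lay at percentile 99.9 among random lists matched on expression, and at 99.6 when the random lists were also matched on gene length. At the 1.5-fold size, 4 were higher, 1 was lower and 23 lay between. Birc5, the chromosomal passenger protein survivin, was 4.06 in wild-type and 9.03 in Rosa26-Foxm1 lung (2.23-fold). The mitotic kinase Aurka was 2.21-fold higher, with 1.49 against 3.31, close to the floor in wild-type lung. The checkpoint kinase Bub1, also close to the floor (1.10 against 2.05), differed by 0.90 on the log2 scale. The cyclin Ccna2 differed by 0.57 and the polo kinase Plk1 by 0.52. Topoisomerase Top2a (-0.06) and the phosphatase Cdc25b (0.11) differed by less than the probe SD, as did Aurkb (0.11, and -0.02 after correction for gene length). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was lower by 1.91-fold at intensities of 1619 and 846. Its probe was far brighter than those of the other mitosis genes named here. Its target was not checked, nor were those of the other probes, and brightness alone does not set the Ube2c value aside. Cdca8 (-0.41) and Kif20a (-0.33) were the next lowest. Cdk1 was below the floor on both arrays, and no probe carried Ccnb1 or Mki67 alone. With the floor at the 75th percentile the median was 0.09, at percentile 86.2.

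S phase and DNA replication genes had a median of 0.16 over 22 genes, at percentile 96.5, inside the middle 95% of random lists, with 94.6 against random lists matched on gene length and 97.8, outside that middle, after correction of the differences for gene length. At the 1.5-fold size 3 were higher and none was lower. The ligase Lig1 differed by 0.76, Uhrf1 by 0.72 and the replication licensing factor Cdc6 by 0.59 with the wild-type array below the floor, against -0.39 for the polymerase Pole and -0.29 for Mcm4. Targets of p53 and inhibitors of cyclin-dependent kinases had a median of 0.12 (percentile 93.9) over 17 genes, and of -0.06 after correction for gene length. Fas (-1.34) was the 1 member past 1.5-fold, beside Cdkn1b at 0.56 (wild type below the floor), Cdkn2d at 0.49 and Perp at -0.53.

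The 32 measured cytokine and chemokine genes had a median log2 difference of 0.69, above the medians of all 10000 random lists, and 18 were at least 1.5-fold higher, 2 lower and 12 between. At the 2-fold size, 14 were higher and none was lower. Besides Cxcl1, the monocyte attractant Ccl7 was at least 4.90-fold higher, with wild type below the floor, and Ccl8 4.55-fold (8.72 against 39.7). Interferon gamma (Ifng, -0.63, Rosa26-Foxm1 below the floor), Tnf (-0.59) and the stromal chemokine Cxcl12 (-0.57) were the lowest. The pair of Cxcl12 probes did not give the same value, and their median was -0.02. With the floor at the 75th percentile the list's median was 0.34, still above all random lists.

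Macrophage genes showed a wide spread around a median of 0.46 over 25 genes, above all 10000 random lists, with 12 genes at least 1.5-fold higher, 2 lower and 11 between. With median scaling that median was 0.73. Gpnmb, Mmp12 and Trem2, a lipid-sensing receptor (3.02 against 22.6, 7.49-fold), were the highest. The lowest was Siglecf, a lectin of alveolar macrophages and eosinophils, with 14.7 in wild-type and 6.15 in Rosa26-Foxm1 lung (2.39-fold lower), and the scavenger receptor Marco was at least 1.68-fold lower, below the floor in Rosa26-Foxm1 lung. Adgre1, which encodes the F4/80 antigen, differed by -0.56. Other genes of the list known from alveolar macrophages, chosen after their values were seen, lay on both sides of 0, with Pparg at 0.45, Chil3 at 0.43, Fabp4 at 0.28, Mrc1 at 0.06, Abcg1 at -0.35 and Cd36 at -0.41.

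Neutrophil and granulocyte genes were lower as a group, with a median of -0.42 over 16 genes at percentile 0.09, although 3 were at least 1.5-fold higher and 3 lower. The C-type lectin Clec4d was 3.80-fold higher and Cd177 and Prtn3 differed by 0.77 and 0.64, whereas the granule protein Ngp (-1.28), the receptor Csf3r (-0.64) and the gelatinase Mmp9 (-0.60) were lower. The mean over the members was -0.13, at percentile 21.4. Among 15 B and plasma cell markers the median of -0.07 was near the centre of the random lists (percentile 48.2), with the mean of opposite sign at 0.14. The 3 highest were plasma cell genes, Jchain at 3.06, Mzb1 at 1.59 and Tnfrsf17 at 1.14 (wild type below the floor). The 3 lowest were B cell genes, the complement receptor Cr2 at -1.62, Ms4a1, which encodes CD20, at -0.96 and Cxcr5 at -0.77. Other B cell genes, chosen after their values were seen, lay on both sides of 0. Blnk was at 0.60 and Cd37 at 0.20, Cd79a at -0.07 and Cd79b at -0.54. A contrast between the 2 cell types was not tested. In all, 4 of the 15 markers were at least 1.5-fold higher and 3 lower. T and NK cell markers had a median of -0.04 (percentile 52.9, mean 0.07) over 20 genes, with 3 higher and none lower. Thy1 (1.04, wild type below the floor), Cd3g (0.76) and Cd28 (0.60) stood at the top and Cd5 (-0.41), Prf1 (-0.38) and Cd3e (-0.34) at the bottom.

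Interferon-induced genes had a median of 0.27 over 22 genes (percentile 99.95), with 5 at least 1.5-fold higher and none lower. Isg15, a ubiquitin-like modifier, was 2.06-fold higher, its protease Usp18 1.73-fold and the immunoproteasome subunit Psmb8 1.59-fold, against -0.32 for both Ifih1 and Rsad2. For MHC class II antigen presentation the median was 0.34 over 8 genes (percentile 99.7), with 2 higher and none lower. H2-Eb1 was 2.04-fold higher, at 18.2 in wild-type and 37.1 in Rosa26-Foxm1 lung, H2-DMa differed by 0.62 and H2-Ab1 by 0.54.

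Endothelial markers differed in 1 direction almost throughout: 28 of 29 were below 0, 15 were at least 1.5-fold lower and none was higher. Their median of -0.59 lay below the medians of all 10000 random lists, also with matching on gene length. Pecam1, the junctional adhesion molecule CD31, had 328 in wild-type and 155 in Rosa26-Foxm1 lung (2.11-fold lower). The receptor Calcrl was 2.22-fold lower and the hypoxia-inducible factor Epas1 2.14-fold lower. Vwf, von Willebrand factor, was the 1 marker above 0, at 0.49 and close to the floor (1.56 against 2.19). Egfl7 (-0.06), Ramp2 (-0.08), Cd93 (-0.18) and Esam (-0.24) differed by less than the probe SD. With median scaling Egfl7 and Ramp2 were at 0.04 and 0.03.

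Fibroblast and extracellular matrix genes were also lower, with a median of -0.29 over 32 genes (percentile 0.26), 7 at least 1.5-fold lower and 1 higher. The nephronectin gene Npnt differed by -0.98, the growth factor receptor Pdgfra by -0.88 and the collagen crosslinking enzyme Lox by -0.87, while tenascin C (Tnc, 0.67), Mfap5 (0.56) and lumican (Lum, 0.52) were above 0. The 14 smooth muscle genes had a median of -0.26 at percentile 3.80, and at 1.84 with median scaling; as a mean it was -0.44. Their lowest members were Sncg, at least 6.10-fold lower, Cald1 (-0.60) and desmin (Des, -0.56), and 2 of the 14 were at least 1.5-fold lower. Growth factor, receptor and oncogene genes had a median of -0.37 over 22 genes (percentile 0.03), with 5 lower and 1 higher. The receptors Fgfr1 (2.07-fold lower) and Fgfr3 (1.78-fold lower) and the ligand Pdgfb (1.94-fold lower) were the lowest. Myc, the proto-oncogene, was 1.57-fold higher, at 5.25 in wild-type and 8.22 in Rosa26-Foxm1 lung.

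Of 18 alveolar type II cell markers, 11 were below 0, and the median was -0.30 at percentile 1.96, but the mean was 0.07. The surfactant protein gene Sftpc had 1228 in wild-type and 856 in Rosa26-Foxm1 lung (-0.52), whereas surfactant protein D (Sftpd) was 1.91-fold higher, with 215 against 411. Chil1, a chitinase-like protein also made by macrophages, was 4.93-fold higher and the fatty acid binding protein Fabp5 3.32-fold. The lowest were complement C5 (Hc, -0.98), the transcription factor Etv5 (-0.71) and the phosphate transporter Slc34a2 (-0.56). In all, 3 type II markers were at least 1.5-fold higher and 2 lower. With median scaling the median was -0.13, at percentile 6.56. It was at percentile 9.60 after correction for gene length and 0.39 against random lists matched on gene length.

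Alveolar type I markers had a median of -0.20 over 13 genes (percentile 14.8), with 5 at least 1.5-fold lower and none higher. That value was -0.07 with loess scaling, and -0.32 as a mean, at percentile 0.54. The basement membrane collagen Col4a3 (at least 2.12-fold lower), the sodium channel subunit Scnn1g (-0.92) and Timp3 (-0.90) were the lowest. Emp2 (0.25), Cldn18 (0.24) and podoplanin (Pdpn, 0.24) were the highest, and the water channel Aqp5 was at 0.10, or -0.09 after correction for gene length. Club cell markers had a median of -0.30 over 18 genes (percentile 1.46), with 3 lower and none higher. Scgb1a1, the main club cell secretory protein, had 2529 in wild-type and 1767 in Rosa26-Foxm1 lung (-0.52, and -0.96 with loess scaling), and Ces1d (-0.86), Cyp4b1 (-0.72) and Aldh1a1 (-0.64) were the lowest. Reg3g (0.44), Scgb3a1 (0.38) and Cldn10 (0.36) were the highest club cell genes. As a mean the club cell value was -0.19, at percentile 7.73, and the median was at percentile 4.61 after correction for gene length and 0.54 with matching on gene length. For ciliated cells the median was 0.11 over 19 genes (percentile 90.7), with 2 higher and 1 lower. Foxj1, the regulator of motile cilia, differed by 0.09, or -0.07 after correction for gene length, Spag17 by 0.84 and Meig1 by 0.76, and Spag16 was at least 2.25-fold lower.

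Goblet and mucous cell genes had a median of 0.30 over 9 genes (percentile 98.0), with 3 at least 1.5-fold higher and none lower. These were Slc26a4, the polymeric immunoglobulin receptor Pigr (21.0 against 112, 5.34-fold) and intelectin 1 (Itln1, 1.84-fold). The mucin Muc4 (-0.24) and Ptger4 (-0.50) were below 0, and Agr2 was at 0.09. With median scaling the percentile was 96.8, after correction for gene length 92.8 and with matching on gene length 98.8, and the mean was 0.76.

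Xenobiotic metabolism genes, which include targets of Ahr and Nrf2, had a median of 0.35 over 22 genes, above all 10000 random lists, with 5 at least 1.5-fold higher and 2 lower. Mgst2 was 2.03-fold higher (12.7 against 25.7), the cystine transporter Slc7a11 at least 1.95-fold and the aldo-keto reductase Akr1b8 1.66-fold. In contrast, Cyp1a1 (-2.54), catalase (Cat, -0.72) and the epoxide hydrolase Ephx1 (-0.39) were lower, and the mean over the list was 0.17.

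Nuclear genes of the mitochondrial respiratory chain had a median of 0.33 over 60 genes, above all 10000 random lists, with 4 at least 1.5-fold higher and none lower. Cox5a was 1.71-fold higher, Ndufb9 1.63-fold and Atp5g2 1.59-fold, against -0.57 for Cox8b, -0.45 for Sdha and -0.37 for Atp5md. After correction for gene length the median was 0.16, still above all random lists. Ribosomal protein genes had a median of 0.15 over 58 genes, also above all 10000 random lists, with none past 1.5-fold. With median scaling that median was 0.38. After correction for gene length it was -0.02, still at percentile 99.7 of random lists. Against random lists matched on gene length the uncorrected median lay at percentile 84.9, so these 2 ways of allowing for length differed. Rpl22l1 (0.58), Rps18 (0.44) and Rpl13a (0.43) were the highest, and Rps27 (-0.47), Rps29 (-0.47) and Rpl38 (-0.38) the lowest. Across 9512 genes the log2 difference had a Spearman rho of -0.27 with genomic gene length, computed across genes, which are not independent replicates.

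Clock genes had a median of -0.13 over 13 genes (percentile 26.3), and of -0.37 (percentile 1.03) with the floor at the 75th percentile, with 1 gene at least 1.5-fold higher and 5 lower. Cry2 was at least 2.31-fold lower, Dbp 2.16-fold lower (77.5 against 35.8) and Nr1d1 1.92-fold lower. Npas2 was 2.40-fold higher, and Arntl, which encodes Bmal1, and Per1 differed by 0.45 and 0.32, Per1 with wild type below the floor. Immediate early and heat shock genes, which respond to tissue handling, had a median of 0.02 over 21 genes (percentile 81.1), and of -0.08 after correction for gene length. Atf3 (1.14) was the 1 member past 1.5-fold, with Jun at -0.57, Fosl2 at -0.50 (Rosa26-Foxm1 below the floor), Ccn1 at -0.34, Dnajb1 at 0.40 and Ier3 at 0.24 (near 0 after correction for gene length).

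Genes of tissues that a lung lobe can carry along showed no group outside the middle 95% of random lists except erythroid genes. These had a median of -0.74 over 4 genes (percentile 0.11), with the haemoglobin gene Hba-a1 at 2074 in wild-type and 1603 in Rosa26-Foxm1 lung (-0.37, and -0.70 with loess scaling), the haem synthesis enzyme Alas2 1.92-fold lower, Fech at -0.53 and the transcription factor Gata1 at least 3.18-fold lower. Cardiac muscle genes, present in pulmonary veins, had a median of -0.20 over 16 genes (percentile 9.76), with percentile 1.56 against random lists matched on gene length and 4.26 after correction of the differences for gene length. Myh6 (-0.96) was the 1 cardiac gene past 1.5-fold, with Myl3 at -0.43, Actc1 at -0.32, Nppa at 0.40 and Sln at 0.32. Skeletal muscle genes had a median of 0.24 over 11 genes (percentile 95.7), and of -0.38 with the floor at the 75th percentile, with 3 genes higher (Mylpf 1.08, Myl1 0.76, Ryr1 0.60) and 1 lower (Tnnt3 -1.01, Rosa26-Foxm1 below the floor). Adipose genes had a median of -0.14 over 6 genes (percentile 31.5), with Plin1 (1.14, wild type below the floor) the 1 higher and Pck1 (-1.26, Rosa26-Foxm1 below the floor) the 1 lower. The 8 mesothelial markers had a median of -0.20 (percentile 17.2), none past 1.5-fold, from -0.57 for Msln to 0.23 for Lrrn4. Only 2 thymocyte genes were measured, Lef1 (-0.24) and Cd1d1 (-0.18).

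The 11 reference genes had a median of 0.25 (percentile 99.3), none past 1.5-fold, against 0.42 with median scaling and 0.17 (percentile 92.4) with loess. After correction for gene length it was 0.09, at percentile 95.1. Gapdh differed by 0.25 and Hprt by 0.36, and Gusb (0.57), Tbp (0.51) and B2m (0.49) were the highest, with Sdha (-0.45), Ywhaz (-0.37) and Pgk1 (-0.18) the lowest. Actb differed by -0.08, but by 0.12 with median scaling. The Y-linked gene Eif2s3y, the 1 sex-linked gene measured, had 7.11 in wild-type and 7.24 in Rosa26-Foxm1 lung. In all, 17 of the 30 lists with at least 3 measured members lay outside the middle 95% of random lists, 10 above and 7 below. Random lists describe how a group stands among the genes of these 2 arrays and do not show how far other pools of mice would differ.

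**Figure D2:**
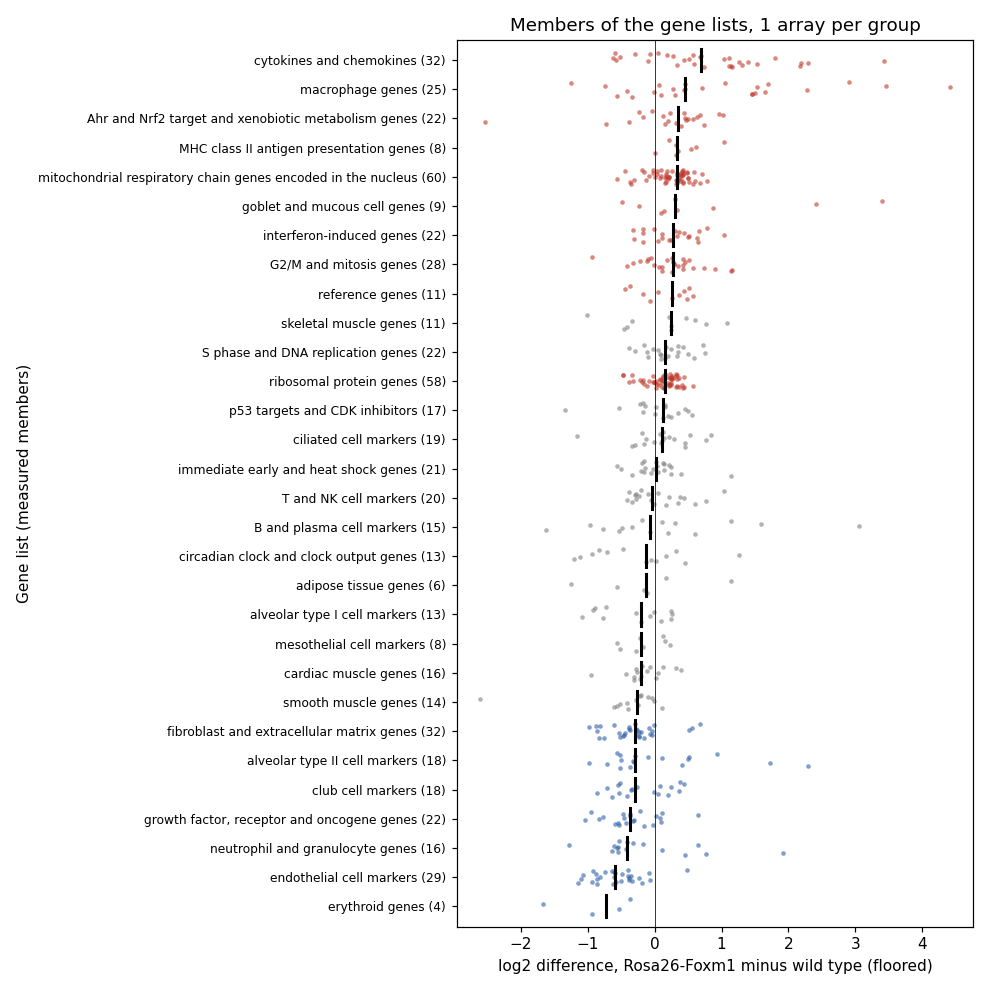
Log2 difference (Rosa26-Foxm1 minus wild type, values below the floor set to it) of each measured member of the 30 gene lists with at least 3 measured members, 1 point per gene, with the list's median as a black bar and the number of measured members in parentheses. Points are red where the median lay above the middle 95% of matched random lists, blue where it lay below and grey where it lay inside. Cytokines and chemokines have the highest median (0.69), and the lowest are those of erythroid genes (-0.74) and endothelial markers (-0.59). The ribosomal median (0.15) is -0.02 after correction for gene length, at percentile 99.7, and the uncorrected median is at 84.9 with matching on gene length.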

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

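The other scalings were planned, but their use as tests of these patterns and the remaining tests were chosen after the results were seen, except the test of gene length for endothelial markers, whose criterion was set before its result was seen.

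Probes without a single listed gene entered no comparison of the report, and among 8018 of them that were measured, 370 were at least 2-fold higher in Rosa26-Foxm1 lung than on the wild-type array and 182 at least 2-fold lower. Probe 630234 was at least 749-fold higher, below the floor at 0.377 in wild-type and 751 in Rosa26-Foxm1 lung, and probe 709407 at least 83.3-fold higher. In the other direction probe 877282 was at least 248-fold lower and probe 824233 at least 28.2-fold lower.

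Macrophage and chemokine genes were higher in Rosa26-Foxm1 lung, while members of the macrophage list ranged from Siglecf at -1.26 through Mrc1 at 0.06 and Chil3 at 0.43 to Gpnmb at 4.42. Scaling between the arrays is argued against, since the lower of both list medians over 3 other scalings was 0.56, for macrophage genes with loess. The macrophage median was 0.46 with quantile normalisation and 0.73 with median scaling, so its size depended on the scaling. Of the 3 other scalings, median scaling and the deposited values are nearly the same setting. Gene length is argued against as the whole cause, since the lists exceeded others matched on expression and length by at least 0.52 (log2). A larger number of macrophages of 1 unchanged kind stays open: the 25 genes had an SD of 1.35, but other lung cells make some of them and a lung holds several kinds of macrophage, so a wide spread does not decide. A single mouse of a pool stays open too, because RNA of 3 mice was pooled with no value per mouse, and an effect of the genotype was not tested.

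Endothelial markers were lower in Rosa26-Foxm1 lung. Longer genes were lower across the arrays, but the endothelial median lay -0.51 from the mean of lists matched on expression and length (SD of such medians 0.08), so length does not account for all of it. Over 3 other scalings, of which median scaling and the deposited values are nearly the same, the endothelial median nearest to 0 was also -0.51. A dilution of all structural lung cells alike by other cells is argued against as the whole cause, for the genes compared on these 2 arrays. The 29 endothelial genes had a median of -0.59 and the 95 genes of other structural lists -0.28. Their difference of -0.31 was at percentile 0.01 of re-divisions of these genes. Re-divisions treat genes as independent, though markers of 1 cell type can vary together. This contrast was also not matched on gene length. Its percentile does not show how far other pools of mice would differ. An effect of the genotype and differences between single mice of the pools stay open and were not tested.

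Clock genes of opposite phase had medians of opposite sign. The 4 genes that peak with Bmal1 had a median of 0.31 and the 9 that peak with Dbp -0.71. The difference of 1.02 was at percentile 98.9 of re-divisions of the 13 genes, whose middle 95% ran from -0.93 to 0.94. These re-divisions treat genes as independent, though clock genes can vary together. The percentile therefore does not show how often 2 pools of mice would differ this way. Single members went against their arm, Per1 at 0.32 (wild type below the floor) and Bhlhe41 at 0.01 among those that peak with Dbp and Cry1 at -0.05 among those that peak with Bmal1. Collection of the pools at different hours is a candidate explanation that predicts such a contrast. An effect of the genotype on the clock predicts it too, and the explanations cannot be told apart with 1 array per genotype and no collection hour in the labels.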

How the results depend on the processing

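Correction for gene length was chosen after the data were seen; the other alternatives were planned. The counts of genes depended most on the floor and the size. At least 2-fold higher and lower were 540 and 532 genes with the floor at the 25th percentile, 44 and 21 at the 75th, and 793 and 829 without a floor, where dim probes enter. At 1.5-fold they were 673 and 804, and at 3-fold 55 and 22. The share of higher genes was 56.6%, between 53.3% and 58.7% over the scalings, 67.7% with the floor at the 75th percentile, 50.4% at the 25th and 48.9% without a floor. Median scaling kept 178 of the 188 higher and 140 of the 144 lower genes, loess 182 and 133, and length correction 161 and 120. Median scaling and the deposited values are nearly the same setting: under both, list medians were -0.13 for type II cells, 0.73 for macrophages and -0.51 for endothelial markers. The macrophage median was 0.56 with loess, 0.60 with length correction and 0.91 as a mean. The chemokine value was 0.34 with the floor at the 75th percentile, 0.54 without a floor and 0.79 as a mean. The mitosis median was 0.087 with the floor at the 75th percentile. As means, club cells had -0.19 and type II cells 0.073, the latter of opposite sign to its median, since a few members are far above 0. The ribosomal median was -0.015 with length correction, of opposite sign, though at percentile 99.7 of random lists. Apart from that construction of the mean, the causes were not tested. Macrophage, chemokine and endothelial medians kept their side of the middle 95% of random lists under 9 of 9 alternatives, club cells under 7 and type II cells under 4. These lists share no genes with others, so leaving out shared genes could change nothing. The median over the probes of a gene left these list medians as they were. Median scaling and the deposited values were also counted separately, so the tallies overstate the number of independent checks. Under the other alternatives 10 counts were within 1.5 times those reported. Of the differences of named genes 1214 moved by less than the probe SD and 17 by more, most of these below the floor on 1 array. The floors at the 25th and 75th percentiles were not tried for single genes. Genes with 1 probe could not move under the median over probes, nor genes above the floor on both arrays without a floor. These numbers therefore say little about how stable single genes are. Of the list medians, 227 moved by less than the SD of random medians, 40 by more without a called sign changing, and 2, the type II and ribosomal values above, by more with a change of sign.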

Other observations

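The genes in this paragraph and the next were chosen after their values were seen, and no theme was tested over them. Further members of the macrophage list were among the 40 genes with the largest differences upward of those that meet the limits on brightness, symbol and probe sign for named genes. The complement subunits C1qa, C1qb and C1qc were 2.73-fold, 2.82-fold and 3.13-fold higher in Rosa26-Foxm1 lung, with C1qa at 73.1 in wild-type and 200 in Rosa26-Foxm1 lung. The protease Ctsk was 4.86-fold higher (15.5 against 75.4), the proton pump subunit Atp6v0d2 2.74-fold and the scavenger receptor Msr1 3.24-fold. Of the cytokine and chemokine list, Ccl6 had 521 in wild-type and 1503 in Rosa26-Foxm1 lung (2.89-fold), and Ccl2 and Cxcl2 were 4.52-fold and 3.49-fold higher. Outside the lists, the cholesterol hydroxylase Ch25h was 5.17-fold higher, the metalloreductase Steap4 4.78-fold and Lrg1, a secreted glycoprotein, 2.59-fold.

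Single genes outside the lists were among the 40 lowest by the same limits. The receptor Notch4 was 2.36-fold lower (8.35 against 3.54), the sphingosine phosphate receptor S1pr3 2.10-fold and the soluble guanylate cyclase subunit Gucy1a1 2.20-fold. The leukocyte integrin Itgal was 2.38-fold lower, the adhesion receptor Adgre5 2.15-fold, at 304 in wild-type and 142 in Rosa26-Foxm1 lung, and the matrix protein gene Ltbp4 2.05-fold. Igfbp3 was 2.39-fold lower and Txnip 1.99-fold. The olfactory receptor gene Olfr1311, by a single probe, was 7.27-fold higher.

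Log2 differences had a median of 0.14 in the shortest of 5 classes of genomic gene length and -0.21 in the longest, with -0.01, -0.07 and -0.11 between. Spearman's rho with length, across genes, was -0.37 in the brighter genes and -0.20 in the dimmer.

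If the Rosa26-Foxm1 mice had carried a stretch of chromosome from another strain, or one that came along with the transgene, 2-fold genes would lie together on a chromosome. The criterion for this test was set before its result was seen, and the way of counting a gene family once was worked out after a cluster of chemokine genes had appeared. Among 20 neighbouring measured genes the largest number past 2-fold was 7, on chromosome 11 (Ccl2, Ccl7, Ccl11, Ccl8, Slfn8, Ccl9 and Ccl6), reached in 7 of 1000 shuffles. With each gene family counted once the largest number was 4 (Insl6, Papss2, Fas and Ch25h). All 1000 shuffles reached a number as large. Counting families once lowered the measured number from 7 to 4 but left the upper bound of the middle 95% of the shuffles at 6. The measured and shuffled orders were thus not lowered alike. This test therefore does not decide whether such a region lay outside the chemokine cluster. A region with few 2-fold genes would not be seen by it.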
